A study of Danio rerio with 6 samples.

How the data were processed

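Total RNA of whole zebrafish embryos was hybridised to Affymetrix arrays, 1 array per sample, in 3 control and 3 Ovo1 morphant samples. The embryos were kept at 28.5 °C until 12 h after fertilisation, and labelled RNA was made from 5 µg of total RNA, per the labels' protocols. Group and replicate number were taken from the sample titles. The design text calls control and morphant embryos transgenic for a sox10 reporter, whereas the sample labels name the reporter only for morphants and call the controls wild type. Whether controls were injected is not stated in the labels. The array's control probe set for a destabilised EGFP read between 33.44 and 44.00 on the 6 arrays, with no difference between the groups (log2 +0.07 ± 0.12). These readings lie near the 25th percentile of the arrays (34.86 to 37.39), so they do not settle which group carried the reporter.

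The authors deposited 1 intensity per probe set and array on a linear scale, made with PLIER in Affymetrix Expression Console 1.1, per the submitters' processing notes. The background, normalization and offset settings of PLIER are not given in the sources used here. The deposited intensities had a median between 132.73 and 154.08 per array, and between 7 and 21 probe sets per array had the value 0. The log2 medians of the arrays ranged over 0.19, above the limit of 0.1 set before the data were examined, so quantile normalization between arrays was applied, on log2(intensity + 16). A pseudocount of 16 shrinks the fold changes of dim probe sets, and all log2 changes are on that scale.

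Of 15617 probe sets, 115 Affymetrix control probe sets were left out and the remaining 15502 tested without a filter on low values. Genes were named through the platform annotation, updated through gene identifiers to the current reference annotation: 10795 probe sets had exactly 1 symbol, 135 several and 4572 none, giving 8793 named genes. A probe set with several symbols was not named. A gene with several probe sets was represented by the one with the highest mean over the 6 arrays, and no named gene had probe sets called in opposite directions.

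Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), morphant minus control, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Of 32 gene lists fixed before the data were examined, 31 had at least 5 measured genes and were tested with camera, two-sided, with a preset correlation of 0.01 between genes. The list of ovo genes had 0 measured members. Named genes followed a rule set before the data were examined: the 12 largest increases and 12 largest decreases among called genes whose groups do not overlap and whose higher group lies above the 25th percentile, up to 4 genes with the smallest p of each list, and a fixed set of neural crest, Wnt, adhesion, Rab and tissue genes. Other list members were named where a list had few called members or was described in full, after their values were seen: bbc3, ccng1, baxa, btg2, mcm7, nog1, bambia, szl, hoxb10a and rpl3. Of the fixed set, wnt3, wnt8a, cdkn1a, rab5a and rab11fip2 are not named in the annotation used and were not analysed here, and 1 further gene is not reported here. Figures were drawn with matplotlib 3.10.9.

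The groups share replicate numbers. Same-numbered control and morphant arrays deviated together from their group means (r = 0.58, 0.46 and 0.54 across probe sets, which are not independent replicates), which met the preset rule of r above 0.1 in every pair, so the numbers were taken to pair the samples. The added poly-A control transcripts followed the numbers as well, with geometric means (pseudocount included) of 483.84, 643.84 and 582.10 in controls 1 to 3 and 465.07, 633.54 and 545.87 in morphants 1 to 3. The first principal component (48.3% of the variance) separated the groups and the second (29.6%) the arrays numbered 1. Blocked values stand beside results whose call they change. Fits that left out 1 array did not use the block.

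The pipeline was tested on simulated data, 15502 probe sets in 3 against 3 arrays. It recovered 47.8% of probe sets changed by a log2 of 0.5, 98.5% of those changed by 1 and 100% of those changed by 2, with 12 false calls among 176. Simulated lists of 20 genes shifted by 0.3 were called in 100% of 100 draws, and 3% of unshifted lists were called. The simulated noise was independent between genes and arrays and held no effect of the replicate number. These rates therefore do not carry over to lists of correlated genes. In the real data the estimated correlation ran from −0.057 (pigment cell) to 0.56 (mitochondrial respiration). Alternatives were the values as deposited, median centring, pseudocounts of 1 and 64, a filter on dim probe sets, eBayes without trend or with robust estimation, array weights, the replicate block, an unmoderated linear model, a 2-fold minimum, an estimated correlation, the mean of a gene's probe sets, and leaving out each array.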

Results

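Gene expression was measured on Affymetrix zebrafish arrays in total RNA of whole embryos of the AB strain at 12 h after fertilisation, the 6-somite stage. The 6 arrays fall into 2 groups of 3, control embryos and Ovo1 morphants, which are embryos injected with a morpholino, an antisense oligomer, against Ovo1, a zinc finger transcription factor. The design text sets the time at the stage when defects of the neural crest, the migratory cells that give rise to pigment cells, peripheral neurons and parts of the skull, are first seen in morphants. The comparison asks which transcripts differ between morphants and controls at that stage. The median probe set intensity lay between 132.73 and 154.08 on the 6 arrays, and the number of arrays limits the precision of every value. Nothing in the labels says that the 3 samples of a group came from separate clutches, so p-values measure the spread between these samples, which may be technical. The targeted gene has no value here, because none of the probe sets is named as an ovo gene in the annotation used, and the knockdown was therefore not checked at the transcript level.

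The gene list with the largest median shift in morphants held growth arrest and apoptosis genes of the DNA damage response, with 12 of 17 members higher. All 5 called members of the proliferation list of 23 were lower, as was the neural crest transcript crestin. The crestin call ended without 3 of the 6 arrays, each left out in turn, in fits without the replicate block. With the block and all 6 arrays the adjusted p of crestin was 0.000192 (limma). No list was called when the correlation between genes was estimated (adjusted p = 0.236 for the damage response and 0.349 for proliferation). The unadjusted camera p of these 2 lists was then 0.00948 and 0.0338. That correlation was estimated from residuals with 4 degrees of freedom, so a list that did not pass is not shown to be unchanged. Of 15502 probe sets, 402 were higher and 484 lower in morphants (limma, Benjamini-Hochberg adjusted p under 0.05, n = 3 per group), and 3299 had an unadjusted p under 0.05. Changes were larger upward, with 99 of the higher and 52 of the lower probe sets changed at least 2-fold, and 34 and 3 at least 4-fold. The 3 morphant arrays lay on one side of the 3 control arrays in 26.0% of all probe sets, where chance gives 10%, and in each of the 886 called ones. With the replicate number as a block, 1367 probe sets were higher and 1524 lower, among them each of the 886. The counts moved by more than 1.5 times whichever array was left out, down to 146 higher and 123 lower without control replicate 3 and up to 830 and 883 without Ovo1 morphant replicate 1.

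**Figure D1:**
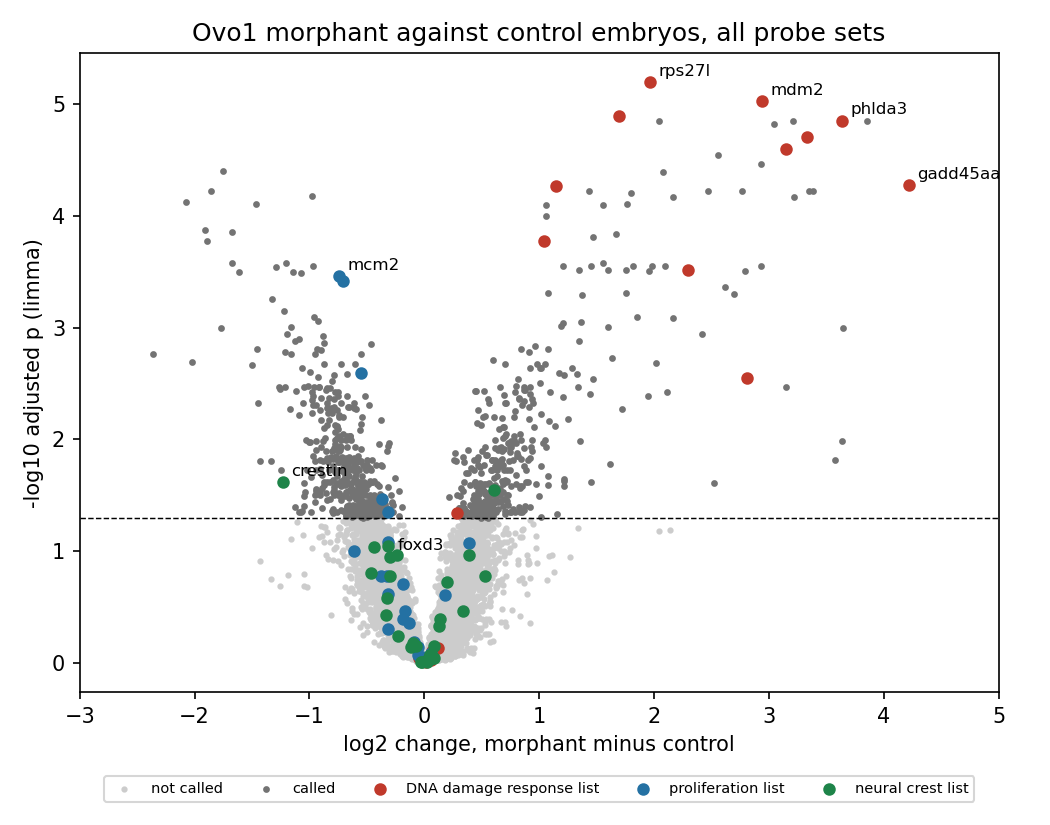
Each point is a probe set, with the log2 change (morphant minus control, 3 arrays each) on the horizontal axis and −log10 of limma's adjusted p on the vertical axis; the dashed line marks an adjusted p of 0.05, and coloured points are the genes of 3 lists. Of the 17 genes of the DNA damage response list, 12 lie to the right and above the dashed line, with gadd45aa at +4.22, while mcm2 and crestin lie to the left at −0.74 and −1.23.

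The named genes with the largest increases included several genes of the DNA damage response. On the log2 scale (difference ± SE), gadd45aa, a growth arrest gene, was higher by 4.22 ± 0.25, phlda3, an inhibitor of Akt signalling, by 3.64 ± 0.17, casp8, an apoptosis protease, by 3.33 ± 0.16, foxo3b by 3.15 ± 0.16, and mdm2, a ubiquitin ligase, by 2.94 ± 0.11. The ubiquitin-like modifier isg15 was higher by 3.86 ± 0.18, the heat shock genes hsp70.3 and hsp90aa1.2 by 3.64 ± 0.59 and 3.15 ± 0.40, and the AP-1 gene fosab by 3.22 ± 0.21. The Wnt agonist rspo1 was higher by 3.21 ± 0.15, the ubiquitin ligase lnx1 by 3.04 ± 0.14 and zgc:101772 by 2.93 ± 0.16. The largest decreases were in lig1, the replicative DNA ligase, at −2.36 ± 0.26, mlst8, a TOR complex subunit, at −2.07 ± 0.14, npm2b at −2.03 ± 0.23, flad1 at −1.89 ± 0.14 and top2b, a DNA topoisomerase, at −1.86 ± 0.12. Below these came anxa1c at −1.77, snx15 at −1.76, tacc2 and ccng2 at −1.67, pank2 at −1.50, and gstm.1 and yju2 at −1.46. Some of these genes were near the floor in 1 group, where the size of a change depends on the pseudocount. With the pseudocount of 16 included, snx15 read 22.70 to 24.32 in morphants. In controls rspo1 read 26.78 to 34.73 and gadd45aa 23.78 to 40.83. The adjusted p of these 24 genes was at most 0.0104, that of hsp70.3, and all 24 stayed past the threshold without each array in turn.

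Of the 17 measured members of the DNA damage response list, 12 were higher and 0 lower, both over all probe sets and adjusted over the list alone, with a median log2 change of 1.70. Besides the genes above they included rps27l (+1.97 ± 0.07), sesn3 (+1.70 ± 0.07), bbc3, ccng1, baxa and btg2, of which btg2 lost its call without 5 of the 6 arrays (adjusted p up to 0.201). The list was called by the set test (camera, adjusted p = 1.53e-17 over 31 lists), but not when the correlation between its genes was estimated from the residuals (adjusted p = 0.236 with an estimated correlation).

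The list of stress and unfolded protein genes also rose, with 7 of 21 members higher, 0 lower and a median of 0.54 (camera adjusted p = 0.000158, and 0.736 with an estimated correlation). The median was 0.27 without Ovo1 morphant replicate 3, and 0.29 without hsp70.3 and hsp90aa1.2, a removal chosen after seeing the data. The list stayed called in both (adjusted p = 0.000331 and 0.00226). Adjusted over the list alone, 10 were higher and 1 lower, and with the replicate block 13 and 1. Among them were the mitochondrial co-chaperonin hspe1 (+0.77 ± 0.13) and the Hsp40 gene dnajb1b (+1.22 ± 0.24), which lost their calls without 1 and 4 of the arrays (adjusted p up to 0.0568 and 0.0945). Of 13 interferon and innate immune genes, 2 were higher, isg15 and isg20 (+1.01 ± 0.12), and 0 lower (3 and 0 with the block). Their list was called with a median of 0.11 (adjusted p = 0.0419, and 0.736 with an estimated correlation), and that call ended with the replicate block (adjusted p = 0.116). It also ended without control replicate 1, control replicate 3 or Ovo1 morphant replicate 1 (adjusted p up to 0.139), and without control replicate 3 the median was 0.057.

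Genes of cell proliferation fell, with 5 of 23 members lower, 0 higher and a median of −0.18 (camera adjusted p = 0.000158, and 0.349 with an estimated correlation). All 5 encode subunits of the replicative helicase: mcm2 at −0.74 ± 0.06, mcm5 at −0.71 ± 0.06, mcm3 at −0.55 ± 0.07, mcm4 at −0.37 ± 0.08 and mcm7 at −0.32 ± 0.08. The calls of mcm4 and mcm7 ended without 5 of the 6 arrays (adjusted p up to 0.131 and 0.172). Adjusted over the list alone, 7 were lower and 1 higher, and with the replicate block 9 and 1.

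In the neural crest list, 1 of 31 measured genes was lower and 1 higher, with the same counts adjusted over the list alone, and 8 were lower and 3 higher with the replicate block. Crestin, a marker of premigratory and migrating crest, was lower by 2.35-fold (−1.23 ± 0.24, adjusted p = 0.0242), with all 3 morphants below all 3 controls. This call ended without control replicate 1, control replicate 3 or Ovo1 morphant replicate 2 (adjusted p up to 0.105), in fits without the replicate block. Without each array in turn the log2 change of crestin stayed between −1.51 and −1.04. With the block and all 3 arrays per group its adjusted p was 0.000192 (limma). The homeobox gene msx2b was higher (+0.61 ± 0.13, adjusted p = 0.0285), and lost its call without each array in turn except Ovo1 morphant replicate 1 (adjusted p up to 0.128). The crest transcription factors foxd3 (−0.30 ± 0.10, adjusted p = 0.111), sox10 (−0.33 ± 0.15, 0.259), tfap2a (−0.24 ± 0.07, 0.108) and sox9b (−0.30 ± 0.11, 0.166) did not pass the test. Each passed it with the replicate block, at adjusted p of 0.0264, 0.0479, 0.0265 and 0.0299. Without Ovo1 morphant replicate 1 the change was −0.18 in sox10 and in sox9b, and without Ovo1 morphant replicate 3 it was −0.49 in sox10. The groups overlapped in snai1b (+0.08 ± 0.22) and twist1a (+0.06 ± 0.14). In mitfa all 3 morphants lay above all 3 controls (+0.17 ± 0.11), and it passed neither test (adjusted p = 0.415, and 0.258 with the block). The list as a whole was not called (camera adjusted p = 0.655), and its median, 0.02, and its mean, −0.05, differed in sign, the test having the sign of the mean. Of 11 pigment cell genes none was called (limma, adjusted p of at least 0.163, 2 with an unadjusted p under 0.05; with the block 1 was lower). Their median was −0.09, and between −0.073 and −0.013 without each array in turn, the last without Ovo1 morphant replicate 1.

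**Figure D2:**
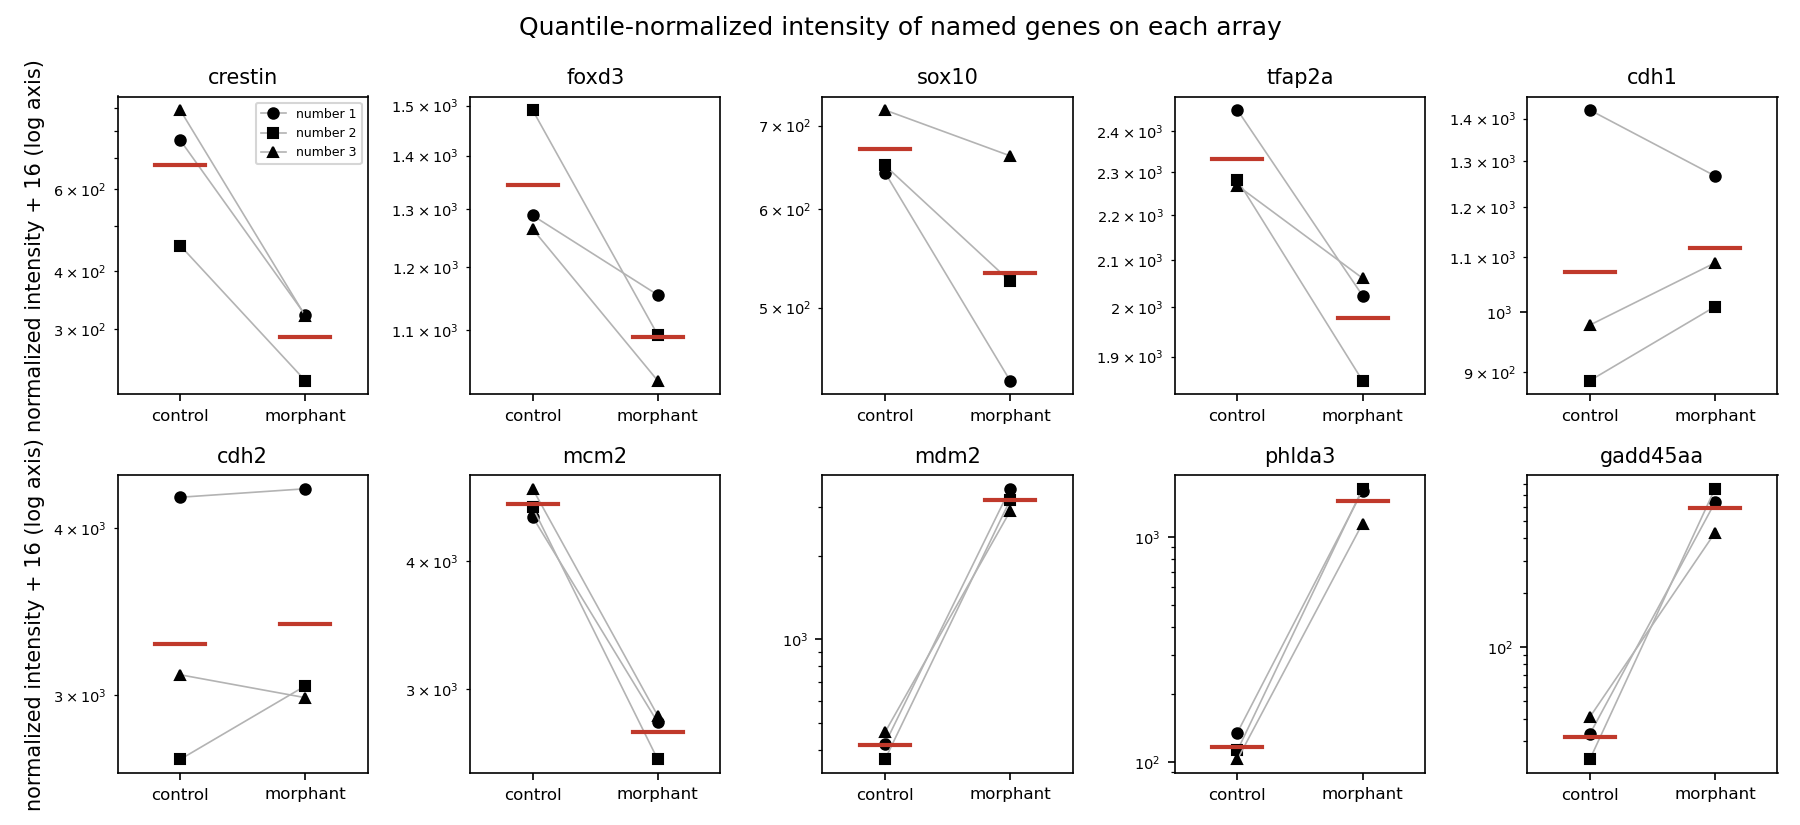
Quantile-normalized intensity with the pseudocount of 16 added (vertical log axes, with a separate range in each panel) of 10 genes on the 3 control and 3 morphant arrays; grey lines join arrays with the same replicate number and red bars are geometric means. All 3 morphants lie below the controls for crestin and mcm2 and above them for mdm2, phlda3 and gadd45aa, while cdh1 and cdh2 overlap.

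The adhesion molecules E-cadherin and N-cadherin showed no difference beyond the spread, with cdh1 at +0.06 ± 0.17 and cdh2 at +0.05 ± 0.18, and cdh2 changed sign with the values as deposited (−0.0047). None of 14 adhesion genes was called (limma, 2 with an unadjusted p under 0.05; with the block 1 was higher). Their median was 0.05, and ran from 0.0071 without control replicate 3 to 0.11 without control replicate 1. In the Wnt pathway list 2 of 41 genes were higher, the inhibitor dkk1b (+0.91 ± 0.13) and the receptor fzd8b (+0.68 ± 0.13), and 1 was lower, gsk3ba (−0.75 ± 0.12). Of 22 genes known as canonical Wnt targets 3 were higher, dkk1b, sp5a and ved, and 0 lower, while lef1 (+0.08 ± 0.19) and axin2 (−0.20 ± 0.14) did not pass. Of these calls only that of dkk1b stayed without each array in turn. That of ved ended without any of the 6 arrays (adjusted p 0.0539 to 0.152), those of sp5a and fzd8b without 4 (up to 0.139 and 0.122), and that of gsk3ba without 2 (up to 0.0675). With the replicate block the counts were 4 higher and 2 lower in the pathway list and 3 and 2 among the targets. Of the 22 targets 6 lay above 0, with a list median of −0.10, opposite in sign to the 3 called genes; the pathway list had a median of 0.06. Neither Wnt list was called (camera adjusted p = 0.345 and 0.653).

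Of 40 genes in the Rab list, the only called gene was rab5if (+0.40 ± 0.10), which is named as a Rab interacting factor and is not a GTPase. The values of rab3c (+0.37 ± 0.11, adjusted p = 0.0839) and rab12 (+0.71 ± 0.26, 0.165) did not pass, and did with the replicate block (0.0308 and 0.00329), while rab11a (−0.16 ± 0.10) and exoc3 (−0.11 ± 0.12) passed in neither fit. The choice of rab3c, rab12 and exoc3 came from knowledge of the study, so their values are not independent evidence of a direction. Of 46 Rab effectors and tethers 1 was lower, vps4b (−0.59 ± 0.12), and of 88 SNARE, coat and sorting proteins 2 were lower, snx15 and copz1 (−0.39 ± 0.09). With the replicate block 5 of the Rab list were higher and 4 lower, 2 and 4 of the effectors, and 11 and 9 of the SNARE, coat and sorting proteins. These 3 lists had medians of −0.0030, −0.03 and 0.03, and none was called (camera adjusted p = 0.820, 0.793 and 0.820). The effectors list took in vps genes by the form of their names, and vps4b is the ATPase of the ESCRT-III complex. The calls of rab5if and vps4b ended without 5 of the 6 arrays and that of copz1 without 3 (adjusted p up to 0.166, 0.118 and 0.165). In the list of planar cell polarity and crest migration 3 of 25 genes were higher, the matrix protease mmp2 (+2.10 ± 0.17), the kinase rock2a (+0.76 ± 0.13) and the proteoglycan sdc4 (+0.46 ± 0.07), and 0 lower, and the list was not called (adjusted p = 0.545; 4 higher and 3 lower with the block).

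Neural genes fell, with 7 of 41 neural plate and neuron genes lower, 0 higher and a list median of −0.18 (camera adjusted p = 0.00100, and 0.736 with an estimated correlation). They included tubb5 (−0.82 ± 0.12), the eye gene rx2 (−0.83 ± 0.16), the midbrain gene en2b (−0.80 ± 0.16), pax6a (−0.57 ± 0.10) and sox2 (−0.41 ± 0.10), and with the block 13 were lower and 2 higher. The median lay between −0.22 without control replicate 1 and −0.096 without control replicate 3, with the list called each time. The tubb5 call stayed without each array in turn, while rx2 and pax6a lost theirs without 3, en2b without 4 and sox2 without 5 (adjusted p up to 0.197). Bmp signalling genes rose, with 7 of 37 higher, 0 lower (10 and 2 with the block) and a median of 0.17 (adjusted p = 0.00249, and 0.236 with an estimated correlation). The 7 were the ligands bmp2b (+0.82 ± 0.11) and bmp3, the receptor bmpr1ab, and the known inhibitors fsta (+0.70 ± 0.10), nog1, bambia and szl. Of these, bmp2b and fsta stayed called without each array in turn, and the others lost their calls without 3 to 5 (adjusted p up to 0.169). Lists called with a single higher member were axial mesoderm and notochord, with shhb (+0.65 ± 0.11) of 17 genes and a median of 0.28, and hatching gland, with klf17 (+0.50 ± 0.10) of 6 and a median of 0.29 (adjusted p = 0.00100 and 0.0367, both 0.736 with an estimated correlation); with the block 5 and 3 of their members were higher. The axial mesoderm median lay between 0.18 without Ovo1 morphant replicate 3 and 0.41 without Ovo1 morphant replicate 1, with the list called each time. The calls of shhb and klf17 ended without 2 and 4 arrays (adjusted p up to 0.0811 and 0.123). Mitochondrial respiration was called with 4 of 84 genes higher, atp5mc1, ndufab1b, atp5mf and cox5aa, and a median of 0.10 (adjusted p = 0.0170, and 0.897 with an estimated correlation), and with the block 18 were higher and 4 lower. Its median lay between 0.034 without control replicate 1 and 0.15 without Ovo1 morphant replicate 1. Of the 4 genes only atp5mc1 stayed called without each array in turn. The hatching gland and mitochondrial calls both ended without control replicate 1, Ovo1 morphant replicate 2 or Ovo1 morphant replicate 3 (adjusted p up to 0.101 and 0.455).

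**Figure D3:**
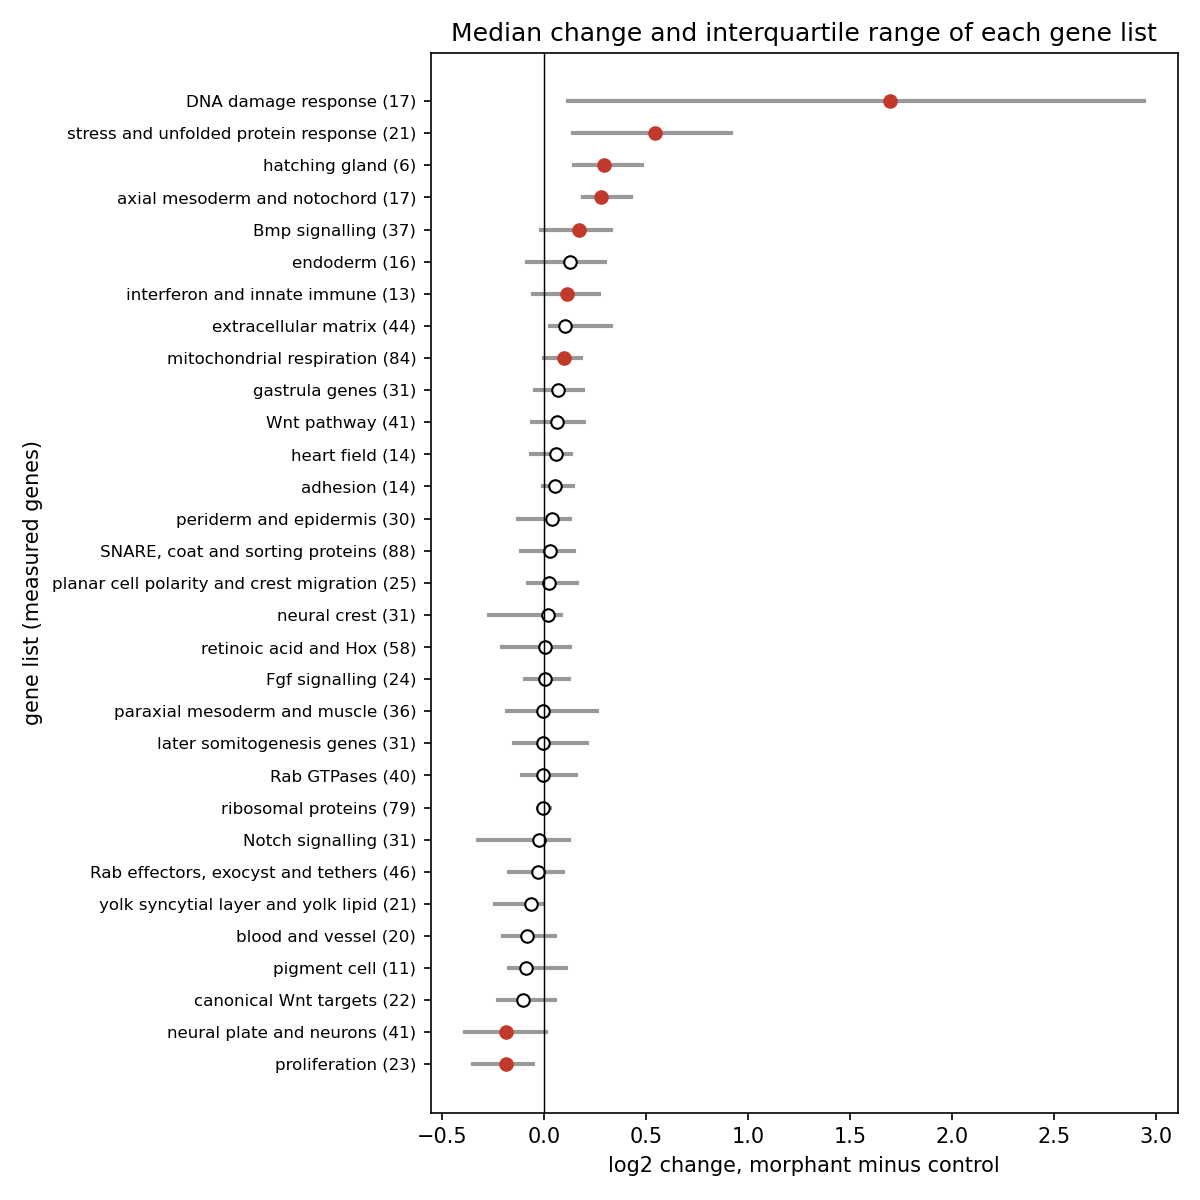
Median log2 change (points; morphant minus control) and interquartile range (grey bars) over the measured genes of each of 31 lists, with the number of genes in brackets. Filled red points are the 9 lists called by camera with the preset correlation, 7 higher and 2 lower, with the DNA damage response list at 1.70; with an estimated correlation 0 were called.

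The other lists were not called (camera adjusted p between 0.0546 and 0.925). In the epidermis list 2 of 30 genes were lower, anxa1c and tp63 (−0.48 ± 0.09), while the periderm keratin krt4 stood at +0.05 ± 0.04. In the retinoic acid and Hox list 6 of 58 genes were lower, aldh1a2, hoxc3a, hoxa9a, hoxa4a, hoxb7a and hoxb10a, and 0 higher (list adjusted p = 0.545). Of 31 Notch genes 3 were higher, among them jag1b (+1.06 ± 0.18), and 2 lower. Of 36 paraxial mesoderm and muscle genes 1 was lower, aldh1a2, with myod1 at +0.24 ± 0.18. Of 20 blood and vessel genes lcp1, a leukocyte actin-bundling protein, was lower (−1.25 ± 0.23) and klf17 higher. Of 31 gastrula genes 3 were higher, bmp2b, tdgf1 and ved, and of 31 genes of later somitogenesis 2 were lower, hoxa9a and crestin. In the yolk list 1 of 21 was lower, tfa. In the ribosomal protein list 3 of 79 were lower, rpl22l1 (−0.98 ± 0.06), rpl10a and rpl3. The 2 that were higher were rps27l, named as a paralogue of a ribosomal protein, and rps6ka3a, a kinase that stands there by the form of its name. Of the called genes named in this paragraph, anxa1c, bmp2b, rpl22l1, rps27l and rps6ka3a stayed called without each array in turn. The other calls ended without 2 to 6 arrays (adjusted p up to 0.189, that of hoxb10a). None of the members of the heart field (14 genes), endoderm (16), Fgf signalling (24) and extracellular matrix (44) lists passed in limma, where 2, 4, 3 and 6 had an unadjusted p under 0.05. With the block 0, 4, 2 and 7 were higher and 0 lower. With the block the other lists of this paragraph had 5 higher and 3 lower (epidermis), 2 and 12 (retinoic acid and Hox), 4 and 9 (Notch), 6 and 4 (paraxial mesoderm), 1 and 2 (blood and vessel), 5 and 2 (gastrula), 6 and 4 (later somitogenesis) and 2 and 4 (yolk). Adjusted over the list alone, the counts of higher and lower genes were 2 and 11 for neural genes, 3 and 0 for axial mesoderm, 2 and 0 for hatching gland, and 3 and 1 for Wnt targets. They were 0 and 0 for the Rab list, 0 and 1 for SNARE and coat proteins, 3 and 2 for planar cell polarity, 3 and 4 for Notch, 2 and 8 for retinoic acid and Hox and 1 and 1 for yolk. The lists not mentioned kept their counts. Median and mean differed in sign in the Rab, SNARE, paraxial mesoderm, later somitogenesis, retinoic acid and Hox and ribosomal lists, all with medians within 0.03 of 0. The test followed the median in the SNARE, paraxial mesoderm, later somitogenesis and ribosomal lists and the mean in the others. The extracellular matrix list had a median of 0.11 and an adjusted p of 0.0546, and was called with the replicate block (0.0175) but with an estimated correlation in neither fit (0.820, and 0.801 with the block). It was also called without 4 of the 6 arrays, each in turn, and not without control replicate 2 or Ovo1 morphant replicate 3 (0.401 and 0.396). Its median rose to 0.30 without the dimmest probe sets.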

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

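The scaling test of the DNA damage response list, the test along the axis between replicate numbers and the count of neighbouring genes along that axis were chosen only after the results had been seen.

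The array's own control probe sets for GAPDH, left out of the comparison, were higher in morphants than in controls: the 3' probe set by 2.22 on the log2 scale (adjusted p = 0.0434), the middle one by 2.01 (0.0431) and the 5' one by 0.94 (0.0469), in limma. The rise was larger at the 3' end than at the 5' end. Whether the groups differed in RNA integrity was not tested. The gene-level probe set of gapdhs stood at +2.04 ± 0.54 (adjusted p = 0.0663, and 0.000385 with the replicate block), that of gapdh at +0.02 ± 0.11. The 4 control probe sets of the muscle actin acta1 ranged from +0.42 to +0.76 and passed only with the block. With the number as a block 7 of the 7 GAPDH and acta1 control probe sets passed. Each number occurs once in each group, so an offset shared by both groups cannot make the difference, and the block leaves it unchanged. A change that differs between numbers was not tested. The acta1 3' control probe set read 861.80 in control and 920.05 in morphant number 1. In number 2 it read 847.08 and 1821.77, and in number 3 1561.59 and 3218.94. A difference in developmental stage stays open. The later somitogenesis list minus the gastrula list gave a median difference of −0.071, with neither list called, which met the outcome written beforehand against a stage difference; that outcome was badly chosen, because 15 of 31 later genes lay above 0 and 16 below, and a median near 0 over members that go both ways decides nothing. Genes at least 2-fold higher in number 3 than in number 1 had a median morphant change above that of genes at least 2-fold lower by 0.498 ± 0.320 (bootstrap SE; 41 and 7 genes), which decides neither way.

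The rise of the DNA damage response list was not set by the scaling between arrays, with a median of at least 1.68 under the other scalings. It does not follow the difference between replicate numbers 3 and 1 inside the groups. Following it would be needed if those numbers and the groups differed in stage in the same way. The median of number 3 minus number 1 was −0.052 in controls and −0.25 in morphants, against 1.70 between groups. The bootstrap SE of the median between groups, 0.74, was taken over the genes of the list and not over arrays. Without each array in turn the median between groups lay between 1.65 and 1.74. A general stress response stays open. The DNA damage response median exceeded that of the stress list by 1.15, with a bootstrap SE over genes of 0.77, under 2 SEs. A side effect of the morpholino without loss of Ovo1 cannot be told apart from an effect of that loss, because the design holds 0 further treated groups such as a second morpholino or a rescue. No pattern is called biological on this basis.

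The groups may also differ in genetic background, as the labels name the transgene for morphants alone. Among 8719 genes with a chromosome position, 595 of them called, 30 pairs of neighbours were both called in the same direction, against a median of 20, a 95th percentile of 27 and a highest value of 41 in 10000 random orders (one-sided permutation p = 0.0207). Of the 12 largest decreases, mlst8, flad1, snx15, tacc2 and ccng2 stood in such pairs, as did crestin (with znf1141). None of the 12 largest increases did. Whether a background difference set the values of the paired genes was not tested. The outcome written beforehand for a background difference named neighbouring called pairs without a direction. That count, added after the other was seen, was 51, against a 95th percentile of 50 in 10000 random orders (one-sided permutation p = 0.0484), so the outcome was met by 1 pair. Neighbouring genes that vary together in any comparison give the same outcome: as many genes taken by their difference between numbers 3 and 1 formed 41 same-direction pairs, against a 95th percentile of 32, and 56 in any direction, against 50. This baseline was added after the first count was seen, and it does not exclude a background difference, since the numbers could mark clutches that differ in background themselves.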

How the results depend on the processing

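Leaving out both arrays numbered 1, the block together with an estimated correlation, the removal of list members, and all runs on the 6 lists of the observations were chosen after seeing the data. The counts of 402 higher and 484 lower probe sets stayed within 1.5 times under other scalings, pseudocounts, the intensity filter and other eBayes settings (278 to 434 and 395 to 509). They moved to 1519 and 1607 with array weights, 1367 and 1524 with the replicate block, 114 and 112 without moderation, 99 and 52 with a 2-fold minimum, and 838 and 911 without both arrays numbered 1. Without each array in turn they ranged from 146 to 830 and from 123 to 883: 235 and 257 without control replicate 1, 154 and 145 without control replicate 2, 146 and 123 without control replicate 3, 830 and 883 without Ovo1 morphant replicate 1, 152 and 133 without Ovo1 morphant replicate 2, and 218 and 229 without Ovo1 morphant replicate 3. Fewer arrays lower the power of a test, and the cause of the rise without Ovo1 morphant replicate 1, the array with the lowest weight (0.34), was not tested. The 9 called lists became 0 with an estimated correlation, alone or with the replicate block, and 7 to 9 in the other settings where the lists were tested, which leaves out robust eBayes, the unmoderated model and the 2-fold minimum. With the replicate block rab40c and snx12 passed (adjusted p = 0.01004 and 0.00287, against 0.0552 and 0.0614), both higher by their brightest probe set (+0.47 and +0.45). The direction depends on the probe set: the mean over the probe sets of each gene, without the block, was −0.11 and −0.41. Of 77 called named genes 41, and of the 9 lists 6, stayed called without each array in turn. The extracellular matrix list was also called as deposited, with median centring and without the dimmest probe sets (adjusted p = 0.0401, 0.0285 and 0.0231, the last with a median of 0.30 against 0.11). It was called as well without control replicate 1 (0.00420), control replicate 3 (0.0343), Ovo1 morphant replicate 1 (0.0175), Ovo1 morphant replicate 2 (0.0308) and both arrays numbered 1 (0.00225, median 0.22). The hatching gland and mitochondrial calls ended as deposited (0.0635 and 0.0806) and with median centring (0.0647 and 0.0908). The interferon call ended with a pseudocount of 1 (0.0501). Without hsp70.3 and hsp90aa1.2 the stress list stayed called, with a median of 0.29 (adjusted p = 0.00226).

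The targeted gene had no value under any setting. Of 10 splits of the 6 arrays into 3 and 3, 1, the real one, gave as many higher probe sets and 1 as many lower ones; the real counts were 402 and 484 and the highest of the other splits 0. With 10 splits no share under 0.05 can be reached. The other splits that part all 3 pairs also gave 0. They had 60 to 204 probe sets at an unadjusted p under 0.05 in limma, against 3299 in the real split. Every split but the real one puts both groups on each side. A difference between the groups then counts as spread and lowers the number of calls, so these counts do not measure chance.

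Over 2521 gene values under alternatives, 2203 kept direction and call, 161 lost and 137 gained a call, and 20 changed sign. Over 559 list values these numbers were 471, 34, 9 and 45. A list's direction was read from its median; this was decided after the values were seen, and by the direction of the set test 30 turn, by either 61. No list that turned was called in either setting. The cause of the turns was not tested. Most of the values lie near 0, apart from those of rab40c, snx12 and gata1a. As deposited, Fgf signalling moved from 0.0080 to −0.0069 and cdh2 to −0.0047. Without the dimmest probe sets, paraxial mesoderm moved to 0.054, later somitogenesis to 0.094 and Fgf to −0.015. With array weights, neural crest moved to −0.0049, pigment cell to 0.018, Rab GTPases to 0.033, later somitogenesis to 0.042, Fgf to −0.034, retinoic acid and Hox to −0.011, ribosomal proteins to 0.0051, snai1b to −0.0020, twist1a to −0.0018, cdh2 to −0.026 and tbxta to 0.035. With the mean of a gene's probe sets, paraxial mesoderm moved to 0.021, later somitogenesis to 0.011, rab40c to −0.11 and snx12 to −0.41, the last past the threshold (adjusted p = 0.0292). Without both arrays numbered 1, Rab GTPases moved to 0.029, paraxial mesoderm to 0.027, blood and vessel to 0.050, gastrula genes to −0.00088, later somitogenesis to 0.048, ribosomal proteins to 0.0039 and gata1a to 0.19. Without each array in turn, ranges that cross 0 were −0.077 to 0.26 for cdh1, −0.12 to 0.23 for cdh2, −0.39 to 0.20 for gata1a, −0.056 to 0.30 for lef1, −0.093 to 0.28 for snai1b, −0.054 to 0.0088 for tbxta and −0.035 to 0.14 for twist1a. For lists they were −0.016 to 0.027 for Fgf, −0.079 to 0.0029 for Notch, −0.033 to 0.063 for Rab GTPases, −0.087 to 0.012 for Rab effectors, −0.00095 to 0.10 for SNARE and coat proteins, −0.16 to 0.074 for blood and vessel, −0.0048 to 0.15 for gastrula genes, −0.0088 to 0.11 for heart field, −0.013 to 0.038 for later somitogenesis, −0.056 to 0.031 for neural crest, −0.0050 to 0.031 for paraxial mesoderm, −0.0023 to 0.044 for retinoic acid and Hox and −0.012 to 0.012 for ribosomal proteins. Among results named in the report, further ranges that keep their sign but move by more than 1.5 times were −0.33 to −0.10 for axin2, −0.17 to −0.017 for exoc3, 0.012 to 0.069 for krt4, 0.11 to 0.22 for mitfa and 0.099 to 0.43 for myod1, and for lists 0.070 to 0.20 for endoderm, 0.027 to 0.063 for epidermis, 0.019 to 0.055 for planar cell polarity and −0.10 to −0.025 for yolk.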

Other observations

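The 6 gene lists here were put together after the called genes had been seen, so their tests describe these arrays and are not independent evidence; none of the 6 passed with an estimated correlation after adjustment. Genes of DNA replication and repair, most of them outside the proliferation list, fell, with 21 of 44 lower and 0 higher (29 and 1 with the replicate block). The median log2 change was −0.34 (camera adjusted p = 2.62e-17, and 0.0993 with an estimated correlation). The list shares orc1, gins2 and rfc4 with the proliferation list, so the 2 lists are not separate. None of these shared genes was called, but gins2 and rfc4 were lower with the block (limma, adjusted p = 0.0208 and 0.0197). Beside lig1 the 21 lower genes included the chromatin remodeller hells (−1.09 ± 0.12), its partner cdca7a (−1.07 ± 0.09) and the clamp loader subunit rfc1 (−1.06 ± 0.13). Also among the 21 were the histone mRNA binding protein slbp (−0.89 ± 0.09) and the mismatch repair gene msh6 (−0.82 ± 0.11). Splicing factors of the SR and hnRNP families also fell, with 12 of 32 lower, 1 higher (hnrnpdl; 15 and 3 with the block) and a median of −0.19 (adjusted p = 2.47e-06, and 0.0993 with an estimated correlation), among them hnrnpua (−0.94 ± 0.20), srsf2b (−0.90 ± 0.10) and srsf1b (−0.88 ± 0.10). The calls of hnrnpdl and hnrnpua ended without 3 and 5 of the 6 arrays (adjusted p up to 0.119).

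Immediate early genes rose, with 8 of 19 higher, 0 lower (10 and 1 with the block) and a median of 0.30 (adjusted p = 3.28e-05, and 0.0993 with an estimated correlation), including fosab, jun (+1.08 ± 0.21; call lost without 5 arrays) and mycb (+0.92 ± 0.11). Among its called genes this list shares btg2 with the DNA damage response list and atf3 with the stress list, so these lists are not separate. Of 12 genes listed for the ESCRT-III membrane scission machinery and its ATPase, 3 were lower and 0 higher (4 and 0 with the block), chmp4bb (−1.22 ± 0.13), chmp4c (−1.05 ± 0.13) and vps4b, and the list was called (adjusted p = 0.000731, and 0.153 with an estimated correlation). The 12 include vps41 and vps45, caught by the start of their names, which are not ESCRT genes. Without them, a run added after seeing the data, 3 of 10 were lower (adjusted p = 0.00104, and 0.153 with an estimated correlation). The call of vps4b ended without 5 arrays. Of 23 glycolysis genes 2 were higher and 0 lower (6 and 1 with the block), aldocb (+2.55 ± 0.13) and pgam1b (+0.63 ± 0.13), with an adjusted p of 0.0158 for the list and 0.153 with an estimated correlation. The list call ended without control replicate 1 (adjusted p = 0.0848), and that of pgam1b without 4 arrays. Of 26 genes of the cytosolic chaperonin and of mitochondrial import 4 were higher, cct2, tcp1, timm29 and tomm40, and 0 lower (8 and 0 with the block; adjusted p = 0.000426, and 0.153 with an estimated correlation). These 4 calls ended without 3 to 5 arrays (adjusted p up to 0.182). The lists other than glycolysis stayed called without each array in turn.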
